A study of Zea mays with 18 samples.

How the data were processed

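Leaves of maize seedlings of the inbred line B73 and of a zmzfp69 line were compared after 0, 24 and 48 h at 4 °C, with 3 libraries in each of 6 groups. Per the labels, seedlings grew at 25 °C with 16 h of light per day, and each of the 3 biological replicates of a group was made from 50 seedlings. Groups, times and replicate numbers were taken from the sample titles, which place the mutant in the B73 background. The treatment field names 4 °C for the 0 h samples too, and 0 h was taken as before transfer. The description field of replicates 2 and 3 of the mutant at 24 and 48 h gives 0 h and was not used, and whether the line is a mutant or a knock-down differs between label fields. The deposited table holds FPKM (fragments scaled by gene length and by the library) for 50118 genes, with gene identifiers, names, descriptions, coordinates and lengths. Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0. Their settings, the strand setting of the counting and the genome build are not given in the sources used here. Coordinates are printed as the deposited table gives them. No gene identifier of the table matched the reference name table (0 matches), so names come from the deposited table, which gave a gene name or protein description for 30156 genes. The table holds 39591 protein-coding genes, 3688 gene models added by the submitters' processing and 409 organelle genes, and 14694 genes had no read in any library. Every column of sample values was used.

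The deposited FPKM values were whole multiples of the value of 1 read per gene length, so whole reads could be recovered (100% of values in each library within a tolerance of 0.01 reads). Recovered totals were 14.8 to 19.1 M reads per library, with a mean of 17.1 M. The total that the FPKM scaling had used was 0.672 to 1.50 times the recovered total, and it matched median-of-ratios size factors up to 1 common factor. Its group means were 1.31, 1.01 and 0.887 times the total in B73 at 0, 24 and 48 h and 1.27, 1.13 and 0.704 times in the mutant. The 10 most abundant genes took 5.43 to 12.6% of reads. Organelle genes took 0.0479, 0.210 and 0.308% of reads on average in B73 and 0.0627, 0.0939 and 0.112% in the mutant at 0, 24 and 48 h. Replicates of a group were compared for libraries deposited more than once. Their recovered reads differed by a chi-square of 40.8 or more per gene, far above sampling noise, so each library counted as 1 replicate.

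FPKM values were tested on the log2(FPKM + 1) scale, on which the fold changes of low genes are understated. Genes with at least 1 FPKM in at least 3 libraries were kept (23141 genes). One linear model of the 6 group means was fitted to all 18 libraries with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3, so that all groups share the estimate of the spread (12 residual degrees of freedom, prior 3.54). Adjusted p-values are Benjamini-Hochberg values within a comparison, and genes with an adjusted p under 0.05 are called changed. The design foresaw a count model only if raw counts were deposited, so the log2 model was the main test. The 12 comparisons were mutant against B73 at each time, each pair of times within a genotype, the genotype by cold interaction at 24 and 48 h, and mutant against B73 averaged over the times. The level of the gene ZmZFP69 was to be checked by name, and 0 names matched.

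Membership in 42 gene lists followed patterns in names and descriptions, and 5 transcription factor lists also took genes by the family column of the deposited table. That column was broad (1094 genes in the WRKY family, against 130 described as WRKY). Lists were tested with limma camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The count of members that passed when p-values were adjusted over the list alone was recorded too. Named genes followed a rule. For each comparison it took the 6 called genes with the largest rise and the 6 with the largest fall that had a mean of at least 5 FPKM in the higher group, a name or description, and groups that did not overlap. It took 3 and 3 for 48 h against 24 h, the interactions and the average, with no condition on overlap for the last 2 kinds. It also took the 2 called members with the largest change in the direction of each list that passed. The text names part of these, from the top of each ordering, and genes called at all 3 times. The lists, rules and tests, and all alternatives except those named as later ones, were fixed before the data were examined.

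The alternatives were a pseudocount of 0.1, no filter, quantile normalization, median-of-ratios size factors, organelle genes left out, the replicate number as a block, limma-voom on recovered reads, only the libraries of the groups compared, and each library left out in turn. Library-total scaling, array weights, transcription factor lists by description and positions of the genes called in the average were added after the data were seen. Positions were tested in 5 Mb windows with a one-sided hypergeometric test, adjusted over 426 windows, and in 10 Mb windows. Comparisons of groups were repeated over all 10 splits of 3 against 3 libraries, or over 100 splits for the interactions and the average. The fitting steps were tested on simulated data with 50 genes at each of 4 fold changes among 23141 genes. For mutant against B73 at 0 h, 0% of the genes changed 2-fold, 34% of those changed 4-fold and 68% of those changed 8-fold were recovered, with 4 unchanged genes called. For the interaction at 24 h these were 0, 16 and 44%, with 4 unchanged genes called, and for the average 44, 82 and 88%, with 9. Other comparisons were not simulated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.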

Results

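RNA from seedling leaves of the maize inbred line B73 and of a zmzfp69 mutant line was sequenced after 0, 24 and 48 h at 4 °C. The line, named for a zinc finger protein gene, is labelled a mutant in some fields and a knock-down in others. Titles place it in the B73 background. The 18 libraries fell into 6 groups of 3, each described as a biological replicate of 50 seedlings. Growth was at 25 °C with 16 h of light per day. Values were FPKM for 50118 genes, of which 23141 reached 1 FPKM in at least 3 libraries and were tested. Reads ranged from 14.8 to 19.1 M per library. Group means were 16.7 ± 0.788, 16.8 ± 1.75 and 18.4 ± 0.584 M for B73 at 0, 24 and 48 h. They were 16.3 ± 1.18, 18 ± 0.989 and 16.4 ± 1.86 M for the mutant (SD, n = 3). No gene in the table or in the reference names used here carried the name zfp69 or ZmZFP69 (0 matches in each), so the level of the targeted gene is not reported and the genotype labels were not checked against it.

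The libraries separated first by time in the cold. The first principal component held 42.2% of the variance and placed the 6 libraries of 0 h between -103 and -89.9. The 3 mutant libraries of 48 h lay between 109 and 112, and the B73 libraries of 48 h at 106, 46.6 and 45.3. Mutant 24 h replicate 2 lay at -68.6, while the other libraries of its group lay at 25.6 and 40.6. The median within-group SD per gene was 0.295, 0.365 and 0.463 on the log2 scale in B73 at 0, 24 and 48 h, and 0.292, 0.447 and 0.404 in the mutant.

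**Figure D1:**
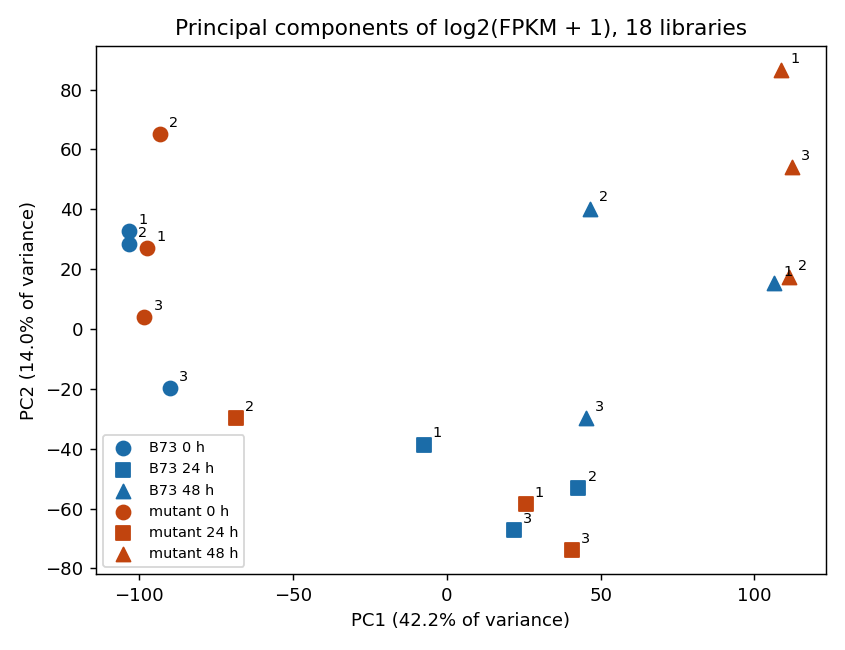
Principal components of log2(FPKM + 1) over the 23141 tested genes. Each point is a library numbered by its replicate (x axis, first component, 42.2% of variance; y axis, second component, 14%), colours give the genotype and shapes the time. Mutant 24 h replicate 2 sits at -68.6 on the first component.

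The deposited values were scaled so that the typical gene had a similar level in all libraries, and the reads assigned to that typical gene differed between groups. With each library rescaled by its total reads instead, the median log2 change of all genes in B73 was -0.30 (24 h against 0 h), -0.44 (48 h against 0 h) and -0.14 (48 h against 24 h), against -0.02, -0.03 and -0.01 with the deposited scaling. In the mutant it was -0.17, -0.63 and -0.42, against -0.02, -0.03 and 0.01, and for the genotypes at 48 h -0.17 against 0.04. Changes are therefore given relative to the typical gene, and for the comparisons of times the counts of higher and lower genes are given with both scalings. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. With the correlation estimated from the data, 0 of the 42 lists passed in any comparison (lowest adjusted p = 0.126, with 1 to 5 lists per comparison at an unadjusted p under 0.05), so each list is given with both adjusted p-values. Genes of near-identical families (histones, ribosomal proteins, gibberellin oxidases, chitinases) can share reads with their copies, and overlapping or antisense genes can share reads where strand was not used in counting, so single members are uncertain. The labels describe a directional library, and the strand setting of the counting is not given in the sources used here.

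**Figure D2:**
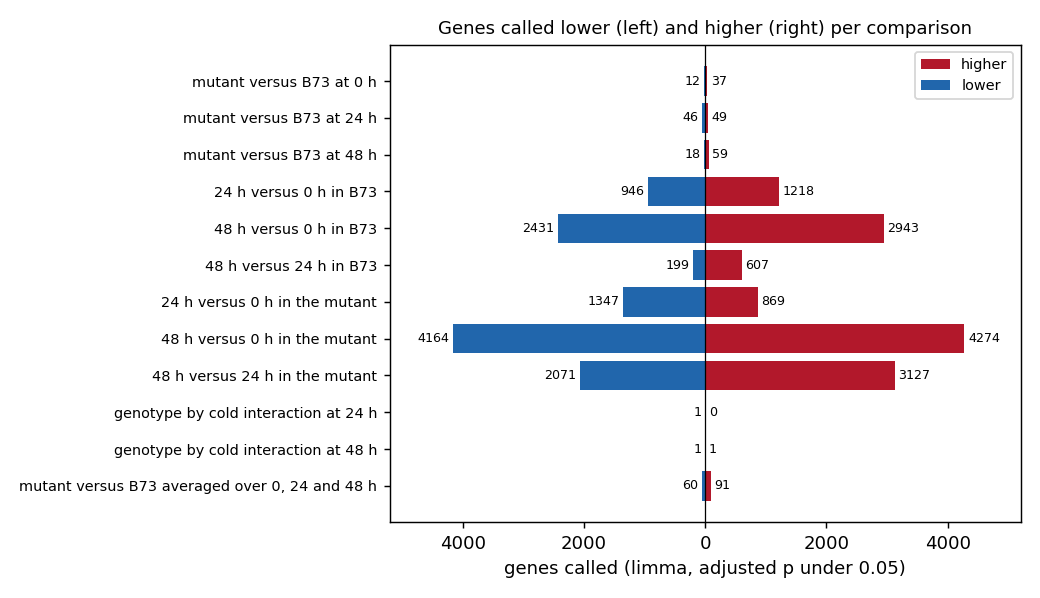
Number of genes that passed in each comparison (x axis, genes with limma adjusted p under 0.05, lower to the left and higher to the right). Comparisons of times within a genotype passed between 806 and 8438 genes, and those of genotypes at a single time between 49 and 95.

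Comparisons of times, first 24 h with 0 h in B73, mix cold with elapsed time, as no group stayed warm. 12-oxo-phytodienoic acid reductase1 (Zm00001d044908, chromosome 9, 6927730 to 6929377) rose from 1.44 ± 2.02 to 905 ± 416 FPKM (mean ± SD, n = 3 here and throughout; log2 fold change 8.76, SE 0.98, adjusted p = 0.000149). Phosphoenolpyruvate carboxylase kinase2 (Zm00001d051156, chromosome 4, 146401256 to 146402641), which phosphorylates the entry enzyme of C4 photosynthesis, rose from 1.22 ± 0.229 to 693 ± 306 FPKM (log2 fold change 8.18). WRKY-transcription factor 114 (Zm00001d036726, chromosome 6, 99175591 to 99177057) rose from 0.874 ± 0.465 to 248 ± 106 FPKM. Zinc finger protein 1 (Zm00001d034642) rose from 0.359 ± 0.381 to 262 ± 162 FPKM. Of the genes that fell, the auxin-responsive gene SAUR36 (Zm00001d021459, chromosome 7, 152719949 to 152720386) fell from 61.1 ± 36.8 to 0.387 ± 0.671 FPKM (log2 fold change -5.34). A histone H2A gene (Zm00001d021300) fell from 30.8 ± 3.63 to 1.29 ± 0.248 FPKM. Peroxidase 52 (Zm00001d046184) fell from 236 ± 102 to 13.6 ± 7.22 FPKM. In all, 1218 genes rose and 946 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 1176 and 824 of them changed at least 2-fold.

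Among the 10 tested DREB/CBF genes, transcription factors that bind cold-response promoters, 6 rose, 0 fell and 4 did not pass. They numbered 8 and 0 adjusted over the list alone (camera adjusted p = 3.10e-07, adjusted p = 0.208 with an estimated correlation). DRE-binding protein4 (Zm00001d036003, chromosome 6, 65322473 to 65323171) rose from 0.243 ± 0.182 to 49.2 ± 13.6 FPKM. AP2-EREBP-transcription factor 36 (Zm00001d021205) rose from 0.508 ± 0.784 to 19.2 ± 4.53 FPKM. Of the 59 genes of jasmonate synthesis and signalling, 23 rose, 1 fell and 35 did not pass. The counts were 25 and 1 adjusted over the list alone (camera adjusted p = 2.11e-08, adjusted p = 0.208 with an estimated correlation). ZIM-transcription factor 14 (Zm00001d048268), of the family that represses jasmonate signalling, rose from 0.122 ± 0.212 to 97.1 ± 119 FPKM. Of the 59 MAP kinase cascade genes, 20 rose, 2 fell and 37 did not pass. These counts were 24 and 3 adjusted over the list alone (camera adjusted p = 2.11e-08, adjusted p = 0.217 with an estimated correlation). Mitogen-activated protein kinase kinase kinase 17 (Zm00001d043740) rose from 0.290 ± 0.115 to 115 ± 96.1 FPKM. Of the 188 calcium sensors and calcium-dependent kinases, 22 rose, 4 fell and 162 did not pass. They numbered 26 and 4 adjusted over the list alone (camera adjusted p = 0.000373, adjusted p = 0.379 with an estimated correlation). Of the 41 dehydrins, LEA and cold-regulated proteins, which are thought to protect cells from drying and cold, 9 rose, 1 fell and 31 did not pass. The counts were 11 and 3 adjusted over the list alone (camera adjusted p = 0.00321, adjusted p = 0.332 with an estimated correlation). Dehydrin DHN1 (Zm00001d017547) rose from 2.63 ± 1.06 to 56.9 ± 19.3 FPKM.

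Of the 33 gibberellin-related genes, 6 rose, 0 fell and 27 did not pass. These counts were 8 and 0 adjusted over the list alone (camera adjusted p = 0.00637, adjusted p = 0.379 with an estimated correlation). The members with the largest change were gibberellin 2-oxidase6 (Zm00001d037724), which rose from 0.0712 ± 0.0148 to 135 ± 105 FPKM, and gibberellin 2-oxidase3 (Zm00001d043411), which rose from 2.14 ± 1.64 to 203 ± 28.9 FPKM. Gibberellin 2-oxidases inactivate the hormone. Of the 123 auxin-related genes, 19 rose, 6 fell and 98 did not pass. They numbered 31 and 9 adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.575 with an estimated correlation). Aux/IAA-transcription factor 19 (Zm00001d013071), of a family that represses auxin signalling, rose from 0.0925 ± 0.0900 to 61.5 ± 30.5 FPKM. Of the 60 carbon fixation and C4 genes, 5 rose, 0 fell and 55 did not pass. The counts were 4 and 0 adjusted over the list alone (camera adjusted p = 0.0399, adjusted p = 0.694 with an estimated correlation). The leading members, phosphoenolpyruvate carboxylase kinase2 and kinase3, phosphorylate an enzyme of the C4 cycle. Of the 122 histone, cyclin and DNA replication genes, 2 rose, 21 fell and 99 did not pass. These counts were 4 and 27 adjusted over the list alone (camera adjusted p = 0.00108, adjusted p = 0.379 with an estimated correlation). Histone H2A.1 (Zm00001d006547) fell from 36.8 ± 3.04 to 3.35 ± 1.15 FPKM. Of the 327 ribosomal protein genes, a list meant for the cytosolic ribosome that also took members named 50S or 30S, 4 rose, 7 fell and 316 did not pass. They numbered 1 and 0 adjusted over the list alone (shifted lower, camera adjusted p = 0.00108, adjusted p = 0.846 with an estimated correlation). None of the 5 transcription factor lists that used the family column passed here or in any other comparison. The same families taken by description alone, a list version chosen after the data were seen, held 32 of 119 ethylene-responsive factors and 15 of 83 WRKY genes that rose, with 6 and 2 that fell (camera adjusted p = 1.62e-06 and 2.12e-05, adjusted p = 0.325 for each with an estimated correlation).

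With library-total scaling, 1105 genes rose and 1859 fell at 24 h in B73, a share of higher genes of 37.3% in place of 56.3%. The count fell from 2164 to 1161 without B73 0 h replicate 1, 1043 without B73 0 h replicate 2, 930 without B73 24 h replicate 2 and 1341 without B73 24 h replicate 3, and rose to 11277 with array weights. Of the 36 genes that the naming rule took here, 27 passed in every alternative and with each library left out.

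After 48 h at 4 °C, more genes changed against 0 h in B73. 12-oxo-phytodienoic acid reductase1 stood at 2246 ± 1854 FPKM (log2 fold change 9.86, SE 0.98, adjusted p = 3.41e-05). Heavy metal-associated isoprenylated plant protein 27 (Zm00001d004138, chromosome 2, 85736310 to 85737686) rose from 0.761 ± 0.159 to 721 ± 530.2 FPKM. Cytochrome P450 81Q32 (Zm00001d012322) rose from 1.87 ± 2.42 to 334 ± 143 FPKM, and a histone H4 gene, H4C7 (Zm00001d026015, chromosome 10, 136050474 to 136050785), rose from 0.821 ± 0.928 to 241 ± 86.6 FPKM. Peroxidase 52 fell from 236 ± 102 to 5.02 ± 1.80 FPKM. SAUR36 fell from 61.1 ± 36.8 to 0.653 ± 0.924 FPKM, and SLOW GREEN 1, a chloroplast protein gene (Zm00001d017621, chromosome 5, 201994341 to 201995299), fell from 68.0 ± 26.8 to 3.14 ± 0.585 FPKM (log2 fold change -4.00). The chalcone synthase gene white pollen1 (Zm00001d007403) fell from 24.6 ± 16.0 to 0.399 ± 0.309 FPKM. In all, 2943 genes rose and 2431 fell.

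Of the 10 DREB/CBF genes at 48 h, 6 rose, 0 fell and 4 did not pass. The counts were 6 and 0 adjusted over the list alone (camera adjusted p = 0.000705, adjusted p = 0.626 with an estimated correlation). Of the dehydrin, LEA and cold-regulated genes, 15 rose, 4 fell and 22 did not pass. These counts were 16 and 5 adjusted over the list alone (camera adjusted p = 0.00515, adjusted p = 0.626 with an estimated correlation). Dehydrin DHN1 rose from 2.63 ± 1.06 to 214 ± 122 FPKM. Of the 32 clock genes, 13 rose, 0 fell and 19 did not pass. They numbered 13 and 0 adjusted over the list alone (camera adjusted p = 0.000705, adjusted p = 0.626 with an estimated correlation). The pseudo-response regulator PRR95 (Zm00001d021291, chromosome 7, 148065548 to 148071232) rose from 1.65 ± 0.940 to 180.3 ± 72.2 FPKM. Of the 169 genes of abscisic acid synthesis and signalling, 44 rose, 16 fell and 109 did not pass. The counts were 47 and 18 adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.626 with an estimated correlation). The leading members were probable protein phosphatase 2C 34 (Zm00001d034109), of a family that holds repressors of the pathway, at 3.09 ± 1.29 and 239 ± 188 FPKM, and abscisic acid 8'-hydroxylase1 (Zm00001d017762), which breaks the hormone down, at 2.32 ± 1.35 and 96.4 ± 44.2 FPKM. Of the calcium genes, 45 rose, 10 fell and 133 did not pass. These counts were 51 and 15 adjusted over the list alone (camera adjusted p = 0.00960, adjusted p = 0.787 with an estimated correlation). Of the MAP kinase genes, 23 rose, 6 fell and 30 did not pass. They numbered 31 and 6 adjusted over the list alone (camera adjusted p = 0.000458, adjusted p = 0.626 with an estimated correlation). Calcium-binding protein CML27 (Zm00001d029028) rose from 67.8 ± 30.2 to 1904 ± 948 FPKM. Of the 89 plastid ribosomal protein genes, 0 rose, 6 fell and 83 did not pass. The counts were 0 and 5 adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.893 with an estimated correlation). 50S ribosomal protein L10 (Zm00001d047760) fell from 34.3 ± 17.1 to 10.7 ± 6.37 FPKM. With library-total scaling, 1907 genes rose and 4837 fell, a share of higher genes of 28.3% in place of 54.8%. The count of 5374 fell to 3307 without B73 0 h replicate 1, 3391 without B73 0 h replicate 2 and 3020 without B73 48 h replicate 1, and rose to 8650 with array weights.

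Between 24 and 48 h in B73, more genes rose than fell. Xylanase inhibitor protein 1 (Zm00001d018966, chromosome 7, 10934095 to 10935021) fell from 122 ± 51.0 to 2.68 ± 0.549 FPKM (log2 fold change -4.98, SE 1.23, adjusted p = 0.0374). The ubiquitin ligase gene ATL45 (Zm00001d051468) fell from 166 ± 170.0 to 6.49 ± 3.20 FPKM. Carboxylesterase 15 (Zm00001d013099, chromosome 5, 4703800 to 4704819) rose from 0.642 ± 0.322 to 94.3 ± 81.6 FPKM. BZIP-transcription factor 74 (Zm00001d020823) rose from 0.430 ± 0.385 to 38.6 ± 42.0 FPKM. Of the jasmonate genes, 0 rose, 6 fell and 53 did not pass. These counts were 0 and 8 adjusted over the list alone (shifted lower, camera adjusted p = 0.000169, adjusted p = 0.790 with an estimated correlation). Jasmonate-induced oxygenase 1 (Zm00001d012456), which inactivates jasmonate, fell from 48.0 ± 11.1 to 5.70 ± 4.95 FPKM. Of the clock genes, 2 rose, 0 fell and 30 did not pass. They numbered 2 and 0 adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.790 with an estimated correlation). Gigantea2 (Zm00001d039589) rose from 1.98 ± 1.95 to 12.7 ± 4.47 FPKM and PRR73 (Zm00001d047761) from 10.3 ± 4.06 to 43.1 ± 8.55 FPKM. Of the 84 epidermis and cuticle markers, 0 rose, 3 fell and 81 did not pass. The counts were 0 and 3 adjusted over the list alone (shifted lower, camera adjusted p = 0.00297, adjusted p = 0.790 with an estimated correlation). Auxin-related, cell wall, benzoxazinoid and vascular lists also passed toward lower levels and the RNA helicase list toward higher ones at camera adjusted p from 0.0282 to 0.0491 (adjusted p from 0.790 to 0.879 with an estimated correlation), and these 5 no longer passed with library-total scaling (adjusted p from 0.0671 to 0.153).

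The 806 genes of that comparison (607 higher, 199 lower) became 523 with library-total scaling (334 higher, 189 lower, a share of 63.9% in place of 75.3%), 457 with limma-voom on recovered reads, 1698 with array weights, and 0 when limma used the 6 compared libraries alone (3328 genes at an unadjusted p under 0.05). The count was 327 without B73 24 h replicate 2, 223 without B73 24 h replicate 3 and 248 without B73 48 h replicate 1, and the call of each of the 18 genes that the naming rule took ended in the fit of the compared libraries.

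In the mutant, 24 h was compared with 0 h. 12-oxo-phytodienoic acid reductase1 rose from 1.47 ± 2.00 to 744 ± 731 FPKM (log2 fold change 7.57, SE 0.98, adjusted p = 0.000541), phosphoenolpyruvate carboxylase kinase3 (Zm00001d017270, chromosome 5, 191243684 to 191245128) rose from 2.47 ± 1.14 to 435 ± 371 FPKM, and SAUR36 fell from 89.0 ± 12.9 to 0.602 ± 0.785 FPKM. Phosphate transporter protein7 (Zm00001d031875) rose from 0.903 ± 0.175 to 167 ± 154 FPKM. A DnaJ chaperone gene (Zm00001d032084) rose from 3.33 ± 1.52 to 234 ± 160.0 FPKM. Indole-2-monooxygenase, an enzyme of benzoxazinoid synthesis (Zm00001d035178, chromosome 6, 8037161 to 8039192), fell from 166 ± 144 to 9.91 ± 15.4 FPKM. CNR7 (Zm00001d034745) fell from 74.7 ± 33.8 to 3.37 ± 4.64 FPKM. In all, 869 genes rose and 1347 fell.

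Of the DREB/CBF genes, 4 rose, 0 fell and 6 did not pass. These counts were 8 and 0 adjusted over the list alone (camera adjusted p = 6.40e-05, adjusted p = 0.897 with an estimated correlation). DRE-binding protein4 rose from 0.475 ± 0.598 to 19.0 ± 15.8 FPKM. Of the MAP kinase genes, 11 rose, 0 fell and 48 did not pass. They numbered 19 and 1 adjusted over the list alone (camera adjusted p = 0.000466, adjusted p = 0.897 with an estimated correlation). Of the clock genes, 6 rose, 1 fell and 25 did not pass. The counts were 8 and 2 adjusted over the list alone (camera adjusted p = 0.00281, adjusted p = 0.897 with an estimated correlation). PRR95 rose from 2.71 ± 1.35 to 145 ± 107 FPKM. Of the 106 RNA helicases and glycine-rich RNA-binding proteins, 8 rose, 3 fell and 95 did not pass. These counts were 9 and 3 adjusted over the list alone (camera adjusted p = 0.00151, adjusted p = 0.897 with an estimated correlation). Of the ribosomal protein genes, 6 rose, 4 fell and 317 did not pass. They numbered 3 and 2 adjusted over the list alone (shifted higher, camera adjusted p = 0.00300, adjusted p = 0.984 with an estimated correlation). Levels overlapped, at 3.12, 2.85 and 3.32 at 0 h and 3.74, 3.39 and 2.91 at 24 h. Defence, autophagy and phenylpropanoid lists were lower. Of the 187 pathogenesis-related and defence genes, 7 rose, 21 fell and 159 did not pass. The counts were 11 and 39 adjusted over the list alone (camera adjusted p = 0.00212, adjusted p = 0.897 with an estimated correlation). Chitinase 1 (Zm00001d049028) fell from 61.7 ± 74.2 to 3.28 ± 3.48 FPKM. Of the 52 autophagy and senescence genes, 0 rose, 6 fell and 46 did not pass. These counts were 0 and 6 adjusted over the list alone (camera adjusted p = 0.000424, adjusted p = 0.897 with an estimated correlation). Autophagy11a (Zm00001d053741) fell from 8.73 ± 4.46 to 2.21 ± 0.988 FPKM. Of the 142 phenylpropanoid and flavonoid genes, 2 rose, 12 fell and 128 did not pass. They numbered 5 and 21 adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.897 with an estimated correlation). Phenylalanine ammonia lyase5 (Zm00001d051163) fell from 20.4 ± 10.4 to 1.49 ± 0.670 FPKM.

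Mutant 24 h replicate 2 stood between the 0 h libraries and the other 24 h libraries on the genes that changed after 24 h of cold in B73. Its mean level on these 2164 genes, signed by the B73 change and centred, was -0.37 on the log2 scale, against 0.56 and 0.79 in the other libraries of its group and -1.26, -1.13 and -1.23 in the mutant at 0 h. The count of 2216 genes rose to 3524 without this library and fell to 883 without replicate 1, 1085 without replicate 3, 1027 without mutant 0 h replicate 1 and 986 without mutant 0 h replicate 2. It was 587 in the fit of the 6 compared libraries and 8952 with array weights. With library-total scaling 804 genes rose and 1736 fell, a share of higher genes of 31.7% in place of 39.2%, and with quantile normalization 1283 rose and 1327 fell (49.2%).

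**Figure D3:**
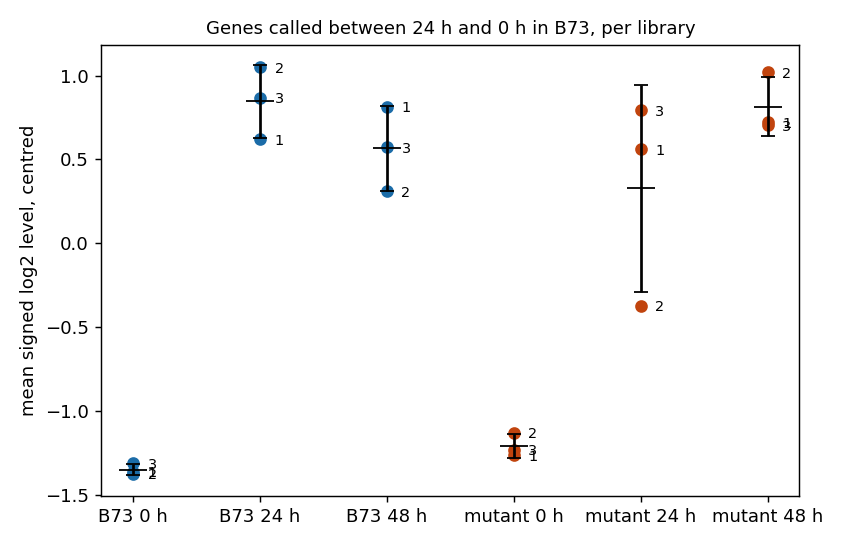
Mean level of the 2164 genes that changed between 24 h and 0 h in B73, signed by the direction of that change and centred over the libraries (y axis, log2). Points are libraries numbered by replicate, and the bar gives the mean and SD of each group of 3 (x axis). Mutant 24 h replicate 2 lies at -0.37, below the other 24 h libraries and above all 0 h libraries. The B73 0 h and 24 h libraries chose the genes and their signs.

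The largest count of changed genes came from 48 h against 0 h in the mutant, with 4274 genes higher and 4164 lower. 12-oxo-phytodienoic acid reductase1 stood at 3696 ± 799 FPKM (log2 fold change 10.82, SE 0.98, adjusted p = 8.43e-06). Its neighbour 12-oxo-phytodienoic acid reductase2 (Zm00001d044906, chromosome 9, 6893412 to 6895013) rose from 6.66 ± 6.94 to 1143 ± 124 FPKM. Xyloglucan endotransglucosylase/hydrolase protein 24 (Zm00001d002410), a cell wall enzyme, rose from 2.57 ± 4.00 to 546 ± 108 FPKM. Lichenase-2 (Zm00001d038049, chromosome 6, 146401513 to 146405955), which cleaves cell wall glucans, fell from 1668 ± 309.6 to 37.5 ± 41.1 FPKM. A histone H1 gene (Zm00001d045478) fell from 122 ± 17.4 to 0.960 ± 0.252 FPKM, and indole-2-monooxygenase fell from 166 ± 144 to 0.0550 ± 0.0953 FPKM (log2 fold change -6.98). Of the carbon fixation and C4 genes, 12 rose, 0 fell and 48 did not pass. The counts were 12 and 0 adjusted over the list alone (camera adjusted p = 0.00975, adjusted p = 0.833 with an estimated correlation). The leading members, phosphoenolpyruvate carboxylase kinase2 and kinase4 (Zm00001d003068), phosphorylate an enzyme of the C4 cycle. Of the 27 mesophyll markers, 7 rose, 0 fell and 20 did not pass. These counts were 7 and 0 adjusted over the list alone (camera adjusted p = 0.0308, adjusted p = 0.833 with an estimated correlation). A chloroplast carbonic anhydrase gene (Zm00001d044095, chromosome 3, 219031166 to 219034215) rose from 7.12 ± 4.90 to 348 ± 47.8 FPKM. Of the dehydrin list, 22 rose, 8 fell and 11 did not pass. They numbered 23 and 8 adjusted over the list alone (camera adjusted p = 0.00975, adjusted p = 0.833 with an estimated correlation). Of the MAP kinase list, 28 rose, 8 fell and 23 did not pass. The counts were 31 and 9 adjusted over the list alone (camera adjusted p = 0.00564, adjusted p = 0.833 with an estimated correlation). Of the DREB/CBF list, 5 rose, 0 fell and 5 did not pass. These counts were 5 and 0 adjusted over the list alone (camera adjusted p = 0.00975, adjusted p = 0.833 with an estimated correlation). With library-total scaling, 2347 genes rose and 8169 fell, a share of higher genes of 22.3% in place of 50.7%, and the mesophyll list no longer passed (adjusted p = 0.0667). Counts without each library in turn ranged from 6231 to 7144, and 24 of the 25 genes that the naming rule took passed in every alternative and with each library left out.

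From 24 to 48 h in the mutant, more genes rose than fell. The chloroplast carbonic anhydrase gene rose from 5.12 ± 3.65 to 348 ± 47.8 FPKM (log2 fold change 6.03, SE 0.62, adjusted p = 5.87e-05), carboxylesterase 15 rose from 2.53 ± 2.70 to 216 ± 45.0 FPKM. Thaumatin-like protein 1 (Zm00001d047938, chromosome 9, 145761337 to 145764192) rose from 1.78 ± 1.53 to 140.2 ± 66.6 FPKM. Catalase3, which breaks down hydrogen peroxide (Zm00001d054044, chromosome 4, 245523681 to 245525759), fell from 403 ± 182 to 15.6 ± 9.33 FPKM. Of the carbon fixation and C4 genes, 9 rose, 0 fell and 51 did not pass. They numbered 5 and 0 adjusted over the list alone (camera adjusted p = 0.0335, adjusted p = 0.825 with an estimated correlation). Of the mesophyll markers, 6 rose, 0 fell and 21 did not pass. The counts were 6 and 0 adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.825 with an estimated correlation). Of the phenylpropanoid and flavonoid genes, 35 rose, 7 fell and 100 did not pass. These counts were 40 and 9 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.825 with an estimated correlation). Trans-cinnamate 4-monooxygenase (Zm00001d012510) rose from 4.53 ± 6.29 to 112 ± 94.5 FPKM. Of the defence genes, 46 rose, 7 fell and 134 did not pass. They numbered 46 and 8 adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.825 with an estimated correlation). Of the dehydrin list, 15 rose, 2 fell and 24 did not pass. The counts were 16 and 2 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.825 with an estimated correlation). Of the ribosomal protein genes, 3 rose, 26 fell and 298 did not pass. These counts were 2 and 8 adjusted over the list alone (shifted lower, camera adjusted p = 5.55e-05, adjusted p = 0.845 with an estimated correlation). Of the RNA helicase list, 9 rose, 21 fell and 76 did not pass. They numbered 9 and 27 adjusted over the list alone (shifted lower, camera adjusted p = 0.0114, adjusted p = 0.825 with an estimated correlation). In all, 3127 genes rose and 2071 fell, against 1552 and 4651 with library-total scaling (25.0% higher in place of 60.2%) and 2261 and 2328 with quantile normalization (49.3%). The count of 5198 fell to 1682 in the fit of the 6 compared libraries, 3059 without mutant 24 h replicate 2 and 2953 without mutant 48 h replicate 1.

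Changes with time ran in the same direction in the genotypes for most genes. Across the 23141 genes, which are not independent replicates, the log2 fold changes of mutant and B73 correlated with Pearson's r = 0.706 and Spearman's rho = 0.633 at 24 h and r = 0.830 and rho = 0.779 at 48 h. The genotypes share no library but share a gene's SE. Of the genes called in B73, 96.8% had the same sign in the mutant at 24 h and 97.7% at 48 h. At 24 h, 499 genes were called higher in both genotypes (45.7 expected from independent lists), 514 lower in both (55.1) and 6 in opposite directions. At 48 h these counts were 2422 (544), 1708 (437) and 6.

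The interaction terms ask whether the change with time differed between genotypes. At 24 h, 1 gene passed, the NAD(P)H-quinone oxidoreductase subunit L gene of the chloroplast (Zm00001d005741, chromosome 2, 185583870 to 185586367), with 40.0 ± 23.8 FPKM at 0 h and 0.617 ± 0.645 at 24 h in the mutant and 0 in all 9 B73 libraries (interaction estimate -4.49 on the log2(FPKM + 1) scale, SE 0.58, adjusted p = 0.0256). At 48 h, 2 genes passed, this gene at 0 FPKM in the mutant (interaction estimate -5.11, adjusted p = 0.00249) and the small nucleolar RNA SNORD25 (ENSRNA049459026, chromosome 5, 190053624 to 190053709), at 20.5 ± 0.767 FPKM in the mutant and 0.212 ± 0.367 in B73 at 48 h (interaction estimate 4.19, SE 0.28, adjusted p = 3.18e-06). SNORD25 was listed at 0 in the other 12 libraries. It is 86 bp long, so its FPKM stand for few reads. At an unadjusted p under 0.05, 1434 and 1725 genes passed. By limma-voom on recovered reads, 1 and 0 genes passed, with library-total scaling 10 and 2, and with quantile normalization 3 at 24 h. Both calls at 48 h ended with limma-voom. The call of the oxidoreductase gene at 24 h ended with a pseudocount of 0.1, with limma-voom, with the replicate block (0 genes called), in the fit of the compared libraries, and without B73 0 h replicate 1 or 2 or B73 24 h replicate 2 or 3. Without single libraries the count at 24 h was 0 (B73 0 h replicate 1 or 2, B73 24 h replicate 3), 2 (mutant 0 h replicate 1, mutant 24 h replicate 2), 3 (B73 0 h replicate 3, B73 24 h replicate 1, mutant 0 h replicate 2), 5 (mutant 24 h replicate 1), 6 (mutant 0 h replicate 3) and 8 (mutant 24 h replicate 3). At 48 h it was 4 (mutant 0 h replicate 1, mutant 48 h replicate 1) and 5 (mutant 0 h replicate 2 or 3, mutant 48 h replicate 3).

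Of the 42 lists, 18 passed in the interaction at 24 h with the preset correlation. At 24 h the 59 jasmonate genes were shifted toward lower values of the interaction term (median log2 difference -0.68; 0 called, 0 and 2 adjusted over the list alone; camera adjusted p = 1.04e-07, adjusted p = 0.247 with an estimated correlation). The RNA helicase list was shifted the other way (median 0.35; 0 called, 1 and 0 adjusted over the list alone; camera adjusted p = 1.04e-08, adjusted p = 0.126 with an estimated correlation), as were the ribosomal protein genes (median 0.61; 0 called, 0 adjusted over the list alone; camera adjusted p = 7.66e-17, adjusted p = 0.427 with an estimated correlation). The other 15 lists had camera adjusted p from 0.000667 to 0.0379 and adjusted p from 0.427 to 0.580 with an estimated correlation, and 1 of these, autophagy, no longer passed with library-total scaling (adjusted p = 0.116). At 48 h the mesophyll (camera adjusted p = 0.000784, adjusted p = 0.876 with an estimated correlation) and phenylpropanoid lists (camera adjusted p = 0.000707, adjusted p = 0.876 with an estimated correlation) were shifted toward higher values of the interaction term, with 0 genes called in either and 4 and 1 phenylpropanoid genes adjusted over the list alone. Mean phenylpropanoid levels at 0 and 48 h were 2.80 and 2.50 on the log2 scale in B73 and 2.67 and 3.00 in the mutant. Those of the mesophyll list were 5.30 and 5.64 in B73 and 5.19 and 6.28 in the mutant. Markers of 3 other cell types lay in the same direction without passing. Shoot meristem and ligule markers averaged 2.89 and 2.68 in B73 and 3.09 and 3.75 in the mutant, epidermis markers 2.52 and 2.10 against 2.58 and 2.56, and vascular markers 2.89 and 2.53 against 2.90 and 3.02 (camera adjusted p = 0.0548, 0.0548 and 0.171). Root and endodermis markers lay the other way, 3.39 and 3.69 against 3.59 and 3.52, and bundle sheath markers were close, 5.51 and 6.14 against 5.68 and 6.42 (camera adjusted p = 0.273 and 0.863). The make-up of the sampled leaves was not tested. The number of lists at 24 h was 7 without mutant 24 h replicate 2, the library that lay toward 0 h.

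At 0 h, taken as before transfer to the cold, the mutant differed from B73 in 49 genes, 37 higher and 12 lower. An added gene model on chromosome 4, from 196519322 to 196521026, annotated as UDP-rhamnose/UDP-galactose transporter 5, stood at 8.92 ± 1.52 FPKM in the mutant against 0.232 ± 0.216 in B73 (log2 fold change 3.01, SE 0.22, adjusted p = 1.34e-05). The oxidoreductase subunit L gene stood at 40.0 ± 23.8 FPKM in the mutant and was listed at 0 in B73 (adjusted p = 2.18e-05), as was the receptor-like kinase gene PERK4 (Zm00001d007487, chromosome 2, 232827656 to 232828330), with 12.7 ± 2.58 FPKM in the mutant. Homeobox-transcription factor 41 (Zm00001d017422) stood at 22.5 ± 16.5 FPKM in the mutant against 0.407 ± 0.391 in B73. Of the 142 phenylpropanoid and flavonoid genes, 0 were higher, 3 were lower and 139 did not pass. The counts were 0 and 3 adjusted over the list alone (the list did not pass, camera adjusted p = 0.149, adjusted p = 0.754 with an estimated correlation). White pollen1, a chalcone synthase gene (Zm00001d007403, chromosome 2, 230953342 to 230957070), stood at 0.317 ± 0.331 FPKM in the mutant against 24.6 ± 16.0 in B73 (log2 fold change -4.14, SE 0.71, adjusted p = 0.0223). Red aleurone1, a flavonoid 3'-hydroxylase gene (Zm00001d017077, chromosome 5, 184494219 to 184496209), stood at 3.33 ± 3.05 FPKM in the mutant against 54.9 ± 10.4 in B73, and flavone synthase1 (Zm00001d047452) at 3.76 ± 0.981 FPKM in the mutant against 30.1 ± 13.4 in B73. Oligopeptide transporter 7 (Zm00001d045519) stood at 3.48 ± 1.07 FPKM in the mutant against 16.4 ± 1.95 in B73.

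Both ribosomal protein lists were shifted lower in the mutant at 0 h. Of the 327 ribosomal protein genes, 1 was higher, 1 was lower and 325 did not pass. These counts were 1 and 1 adjusted over the list alone, with a median log2 difference of -0.55 (camera adjusted p = 1.46e-25, adjusted p = 0.618 with an estimated correlation). Of the 89 plastid ribosomal protein genes, 0 were higher, 1 was lower and 88 did not pass. They numbered 0 and 1 adjusted over the list alone (camera adjusted p = 4.28e-12). 50S ribosomal protein L25 (Zm00001d013730) stood at 1.88 ± 0.247 FPKM in the mutant against 7.33 ± 1.98 in B73. The autophagy list was shifted higher with 0 members called (camera adjusted p = 0.00217, adjusted p = 0.690 with an estimated correlation). So were the dehydrin, trehalose and raffinose, and abscisic acid lists (camera adjusted p = 0.0164, 0.0159 and 0.0202, adjusted p = 0.618 for each with an estimated correlation). Adjusted over the list alone, 4 abscisic acid genes were higher. The count of 49 genes was 31 with a pseudocount of 0.1, 112 with no filter, 7323 with array weights and 18 in the fit of the 6 compared libraries, and 30, 25 and 25 without B73 0 h replicate 1, 2 or 3 and 28 and 31 without mutant 0 h replicate 1 or 2. The count of 7323 rests mostly on 1 library per genotype, mutant replicate 1 and B73 replicate 2. Of the 12 genes that the naming rule took, the transporter model alone passed in every alternative and with each library left out, and the call of each flavonoid gene named ended with a pseudocount of 0.1 and without B73 0 h replicate 1, 2 or 3 or mutant 0 h replicate 2.

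At 24 h, 49 genes were higher and 46 lower in the mutant than in B73. Aquaporin TIP3-1 (Zm00001d048520, chromosome 9, 157714272 to 157715705), a water channel of the vacuole membrane, stood at 54.9 ± 25.6 FPKM in the mutant against 2.38 ± 1.01 in B73 (log2 fold change 3.98, SE 0.63, adjusted p = 0.0105), and histone H2A.5 (Zm00001d019045, chromosome 7, 14093201 to 14093758) at 20.9 ± 4.82 FPKM in the mutant against 1.65 ± 1.94 in B73. Myb transcription factor 42 (Zm00001d053220) stood at 9.13 ± 2.78 FPKM in the mutant against 1.05 ± 0.850 in B73. Cytochrome P450 78A9 (Zm00001d027537, chromosome 1, 7714226 to 7716606) was lower, at 0.130 ± 0.225 FPKM in the mutant against 42.2 ± 18.5 in B73 (log2 fold change -5.19, SE 0.82, adjusted p = 0.0105), as were WRKY-transcription factor 74 (Zm00001d044010), at 1.31 ± 0.768 FPKM in the mutant against 28.3 ± 14.3 in B73, and AP2-EREBP-transcription factor 63 (Zm00001d042593), at 0.361 ± 0.395 FPKM in the mutant against 9.57 ± 2.75 in B73. The transporter WAT1-related protein At5g07050 (Zm00001d045572) stood at 11.4 ± 6.44 FPKM in B73 and was listed at 0 in the mutant.

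Of the 42 lists, 14 were shifted lower and 2 higher at 24 h with the preset correlation. Of the 59 jasmonate genes, 0 were higher, 0 were lower and 59 did not pass. The counts were 0 and 4 adjusted over the list alone (shifted lower, camera adjusted p = 2.71e-06, adjusted p = 0.387 with an estimated correlation). Of the 142 phenylpropanoid and flavonoid genes, 0 were higher, 1 was lower and 141 did not pass. These counts were 1 and 7 adjusted over the list alone (shifted lower, camera adjusted p = 2.95e-05, adjusted p = 0.387 with an estimated correlation). The called member, cinnamoyl-CoA reductase-like SNL6 (Zm00001d044104), stood at 2.10 ± 1.92 FPKM in the mutant against 13.96 ± 4.43 in B73. Of the 10 DREB/CBF genes, 0 were higher, 0 were lower and 10 did not pass. They numbered 0 and 0 adjusted over the list alone (shifted lower, camera adjusted p = 0.0156, adjusted p = 0.552 with an estimated correlation). DREB/CBF levels of replicates 1, 2 and 3 overlapped, at 3.16, 2.29 and 4.52 in the mutant and 3.88, 4.50 and 4.38 in B73. Of the 123 auxin-related genes, 0 were higher, 1 was lower and 122 did not pass. The counts were 1 and 7 adjusted over the list alone (shifted lower, camera adjusted p = 0.0126, adjusted p = 0.552 with an estimated correlation). The RNA helicase list was shifted higher with 0 members called (camera adjusted p = 9.33e-07, adjusted p = 0.251 with an estimated correlation), as was the clock list, with 3 genes higher adjusted over the list alone (camera adjusted p = 0.0154, adjusted p = 0.552 with an estimated correlation). Lists of photosystems, carbon fixation, peroxidases, glutathione transferases, calcium sensors, MAP kinases, defence, nitrogen assimilation, epidermis and mesophyll had camera adjusted p from 0.00276 to 0.0478 (lower, adjusted p from 0.552 to 0.871 with an estimated correlation), and that of calcium sensors was 0.0504 with library-total scaling and 0.0557 with the replicate block. The number of lists was 7 without mutant 24 h replicate 2, which lay toward 0 h, and 9 without B73 24 h replicate 2. The count of 95 genes was 52 with limma-voom, 801 with array weights and 1 in the fit of the 6 compared libraries. It was 196, 28 and 24 without B73 24 h replicate 1, 2 or 3, and 47, 47 and 208 without mutant 24 h replicate 1, 2 or 3, and with library-total scaling 47 genes were higher and 28 lower (62.7% in place of 51.6%). None of the 17 genes that the naming rule took passed in the fit of the compared libraries.

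At 48 h, 59 genes were higher and 18 lower in the mutant. Knotted1 induced1 (Zm00001d022630, chromosome 7, 181798165 to 181799397) stood at 1504 ± 947 FPKM in the mutant against 37.6 ± 22.8 in B73 (log2 fold change 5.12, SE 0.86, adjusted p = 0.0152). CBL-interacting protein kinase 7 (Zm00001d033316, chromosome 1, 258846263 to 258847552), a kinase of calcium signalling, stood at 219.5 ± 75.5 FPKM in the mutant against 12.0 ± 8.77 in B73, and hemoglobin1 (Zm00001d048020) at 45.0 ± 20.4 FPKM in the mutant against 2.41 ± 1.26 in B73. A nitrate reductase gene (Zm00001d052139) stood at 21.0 ± 13.8 FPKM in the mutant against 0.827 ± 0.697 in B73, and SNORD25 at 20.5 ± 0.767 FPKM in the mutant against 0.212 ± 0.367 in B73 (adjusted p = 1.86e-08). Homeobox-transcription factor 37 (Zm00001d013547, chromosome 5, 14028554 to 14034708) was lower, at 3.89 ± 0.491 FPKM in the mutant against 17.5 ± 1.52 in B73 (log2 fold change -1.92, SE 0.24, adjusted p = 0.00209), as was a BTB/POZ domain gene (Zm00001d035208), at 4.78 ± 0.818 FPKM in the mutant against 12.0 ± 1.204 in B73.

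At 48 h, 11 lists were shifted higher and 2 lower with the preset correlation, or 5 lists in all without mutant 48 h replicate 2. Of the 84 epidermis and cuticle markers, 1 was higher, 0 were lower and 83 did not pass. These counts were 3 and 2 adjusted over the list alone. Of the 10 shoot meristem and ligule markers, 1 was higher, 0 were lower and 9 did not pass. They numbered 2 and 0 adjusted over the list alone (camera adjusted p = 0.00647 and 0.0101, adjusted p = 0.565 for each with an estimated correlation). The 27 mesophyll markers averaged 6.28 ± 0.313 on the log2 scale in the mutant and 5.64 ± 0.232 in B73, with 0 called (camera adjusted p = 0.00647, adjusted p = 0.565 with an estimated correlation). The phenylpropanoid list (1 higher adjusted over the list alone) and the dehydrin list were also shifted higher, and the ribosomal protein list lower. Each had 0 called (camera adjusted p = 0.00647, 0.00647 and 7.50e-13, adjusted p = 0.565 for each with an estimated correlation). Ribosomal list levels overlapped, at 2.89, 3.98 and 3.26 in B73 and 3.31, 2.68 and 2.83 in the mutant. Lists of carbon fixation, trehalose and raffinose, membrane lipids, cell wall, defence, vascular markers (higher) and RNA helicases (lower) had camera adjusted p from 0.0101 to 0.0496 (adjusted p = 0.565 with an estimated correlation), and with the replicate block those of membrane lipids and vascular markers stood at 0.0532. That of membrane lipids was 0.0541 with library-total scaling. With a pseudocount of 0.1, 27 genes were higher and 25 lower (51.9% higher in place of 76.6%), and 36 of the 77 genes kept their call. The count of 77 genes was 23 with limma-voom, 26 with library-total scaling, 43 with array weights and 4 in the fit of the 6 compared libraries. It was 126, 183 and 36 without B73 48 h replicate 1, 2 or 3 and 158 without mutant 48 h replicate 3. Of the 12 genes that the naming rule took, SNORD25 alone passed in every alternative and with each library left out, while the call of knotted1 induced1 ended with library-total scaling and without mutant 48 h replicate 1 or 2.

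At all 3 times, 6 genes differed the same way between genotypes, 4 higher and 2 lower in the mutant, in tests that share a gene's SE. Zm00001d019002, a protein-coding gene with no name (chromosome 7, 12662001 to 12662237), stood at 4.04 ± 2.08, 12.8 ± 9.08 and 4.85 ± 3.21 FPKM in the mutant against 116 ± 61.4, 318 ± 25.4 and 184 ± 55.8 in B73 at 0, 24 and 48 h (log2 fold changes -4.50, -4.91 and -5.08). YABBY 2 (Zm00001d013661, chromosome 5, 16648811 to 16650019), a transcription factor of a family that patterns leaves, stood at 1.77 ± 0.369, 3.80 ± 0.681 and 1.76 ± 1.21 FPKM in B73 and was listed at 0 in all 9 mutant libraries. The transporter model on chromosome 4 stood at 8.92 ± 1.52, 6.81 ± 1.498 and 6.14 ± 1.02 FPKM in the mutant against 0.232 ± 0.216, 0.0685 ± 0.119 and 0.0597 ± 0.103 in B73. An added model on chromosome 1, from 105940386 to 105941388, stood at 12.6 ± 1.19, 10 ± 2.47 and 5.22 ± 2.34 FPKM in the mutant against 0.668 ± 0.860, 0.617 ± 0.871 and 0.493 ± 0.275 in B73. Polyadenylate-binding protein-interacting protein 11 (Zm00001d037395, chromosome 6, 124278820 to 124284218) stood at 5.19 ± 1.54, 2.07 ± 0.579 and 3.59 ± 2.09 FPKM in the mutant, and an added model annotated as a pentatricopeptide repeat protein (chromosome 6, 163305513 to 163309953) at 2.82 ± 0.842, 3.64 ± 1.70 and 2.70 ± 0.597, both listed at 0 in all B73 libraries. Each of the 6 genes lay in a 5 Mb window of its own, where 1 gene of 6 cannot pass after adjustment (0 of 426 windows by a one-sided hypergeometric test, 6 at an unadjusted p under 0.05). With 10 Mb windows 0 passed (4 unadjusted). The count was 4 with library-total scaling and 5 with no filter.

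**Figure D4:**
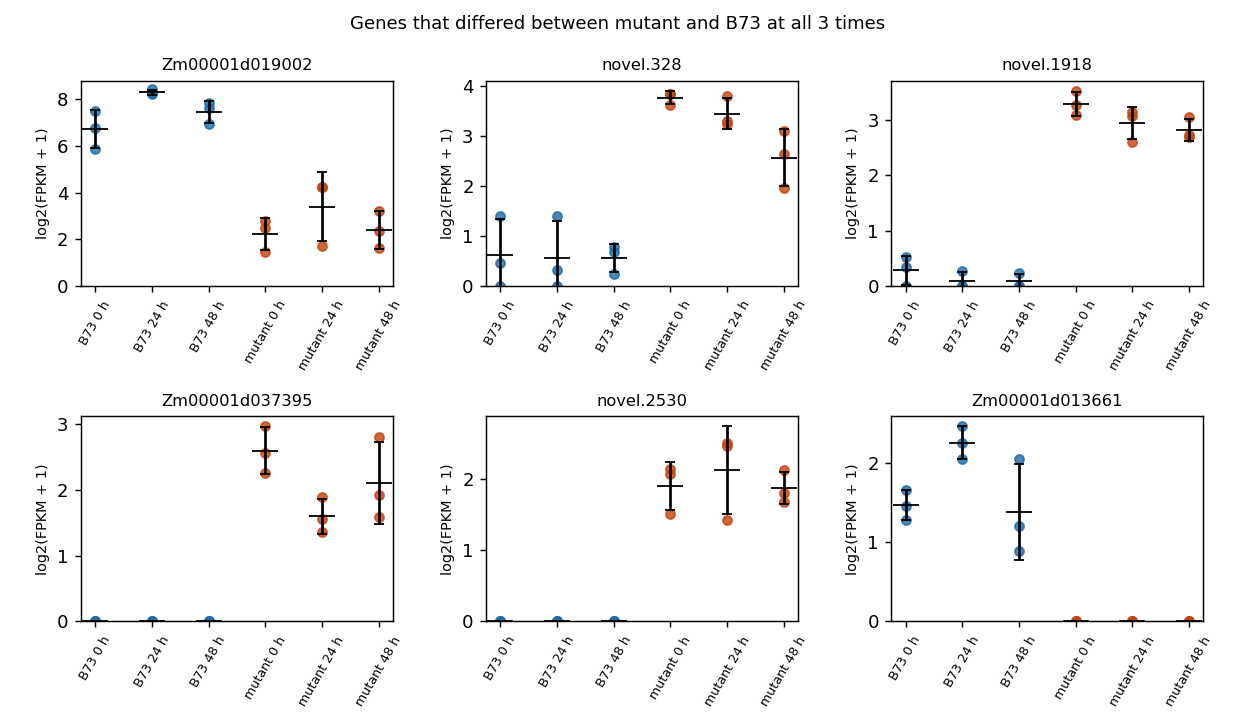
The 6 genes called at all 3 times, as log2(FPKM + 1) (y axis) per library in each group (x axis). Points are libraries and bars give the mean and SD of 3, with B73 in blue and the mutant in orange. Panels are titled with gene identifiers as the deposited table gives them, and 2 genes lie at 0 in all B73 libraries and 1 in all mutant libraries.

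Averaged over the 3 times, 91 genes were higher and 60 lower in the mutant. The transporter model had a log2 fold change of 2.87 (SE 0.13, adjusted p = 8.11e-09), knotted1 induced1 of 2.68 and CBL-interacting protein kinase 7 of 2.51. Resistance to sugarcane mosaic virus1 (Zm00001d035390, chromosome 6, 24034207 to 24035363) was lower, with 47.9 ± 16.9, 38.4 ± 66.1 and 7.70 ± 13.2 FPKM in the mutant against 149.6 ± 32.2, 294 ± 289.6 and 216 ± 136 in B73 (log2 fold change -4.28, SE 0.86, adjusted p = 0.0314), and its call ended with a pseudocount of 0.1, with no filter and without each of 13 libraries in turn (every library but B73 24 h replicate 2, B73 48 h replicate 1, mutant 0 h replicate 3, mutant 24 h replicate 3 and mutant 48 h replicate 2). Salicylic acid-binding protein 2 (Zm00001d009398) had a log2 fold change of -3.35. Of the 22 trehalose and raffinose genes, 0 were higher, 0 were lower and 22 did not pass. The counts were 6 and 2 adjusted over the list alone (shifted higher, camera adjusted p = 0.00672, adjusted p = 0.831 with an estimated correlation). Of the 10 DREB/CBF genes, 0 were higher, 0 were lower and 10 did not pass. These counts were 0 and 2 adjusted over the list alone (shifted lower, camera adjusted p = 0.0146, adjusted p = 0.987 with an estimated correlation). The ribosomal protein and plastid ribosomal protein lists were shifted lower (camera adjusted p = 1.36e-17 and 5.40e-06). The starch and dehydrin lists were higher (camera adjusted p = 0.0235 and 0.0155). Each had adjusted p = 0.987 with an estimated correlation. The ribosomal protein list averaged higher in the mutant at 24 h (3.35 against 3.25 in B73). The plastid list did so at 48 h (4.25 against 4.21). Each averaged lower at the other times. A position test added after the data were seen placed 9 of the called genes among the 50 tested genes of chromosome 7 from 10000001 to 15000000, with Zm00001d019002 and histone H2A.5 among them. It placed 7 among the 38 tested genes of chromosome 6 from 5000001 to 10000000, with the BTB/POZ domain gene among them. The count of 151 genes was 616 with array weights, 94 and 88 without B73 0 h replicate 1 or 2, 98 without B73 24 h replicate 3 and 97 without B73 48 h replicate 3.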

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

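The interaction tests of this part were fixed before the data were examined, and the runs with library-total scaling and array weights were chosen after the results were seen. The interaction term passed in 2 genes, and neither call held in every alternative. The gene annotated as the chloroplast protein NAD(P)H-quinone oxidoreductase subunit L (Zm00001d005741, chromosome 2, 185583870 to 185586367) had an interaction estimate of -4.49 at 24 h (SE 0.58, limma adjusted p = 0.0256) and -5.11 at 48 h (adjusted p = 0.00249). It stood at 56.5, 12.7 and 50.9 FPKM in the mutant at 0 h and at 0.565, 1.29 and 0 FPKM at 24 h, was listed at 0 in the 3 mutant libraries of 48 h, and was listed at 0 in all 9 B73 libraries. The small nucleolar RNA SNORD25 (ENSRNA049459026, chromosome 5, 190053624 to 190053709) had an interaction estimate of 4.19 at 48 h (SE 0.28, adjusted p = 3.18e-06). It stood at 21.1, 20.6 and 19.6 FPKM in the mutant at 48 h and 0.636 FPKM in 1 B73 library at 48 h, and was listed at 0 in the other 14 libraries. The call at 24 h ended with a pseudocount of 0.1, with the replicate block (0 genes called in each), with limma-voom on recovered reads and in the fit of the compared libraries. Both calls at 48 h ended with limma-voom (0 genes called).

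Of 100 splits of the libraries, 23 called at least 1 gene in the interaction at 24 h, the real split included, and the highest other split called 124, which may point to a structure of the samples other than genotype. Its source was not tested. At 48 h, 15 of 100 splits called at least the real 2 genes, and the highest other split called 10. Chance is excluded for neither count. Of the list counts, 6 of 100 splits gave at least the real 18 lists at 24 h (highest other 23) and 72 of 100 gave at least the real 5 at 48 h (highest other 16), so chance is not excluded there either.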

How the results depend on the processing

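Library-total scaling, array weights and lists by description were chosen after the data were seen. Of 210 pairs of a named gene and a comparison, 108 kept their call in every run with another setting or a library left out, 116 did so in every run with all libraries, and 0 turned direction. The cause of a moved count was not tested, except that runs with fewer libraries have fewer replicates. Median-of-ratios size factors differ from the deposited scaling by 1 common factor (at most 2.02% from it), so they say nothing about stability. Depth limited the reads of low genes, and simulated 2-fold changes between the genotypes at 0 h were not recovered (0%).

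With array weights the counts of called genes moved to 7323, 801 and 43 for the genotypes at 0, 24 and 48 h, to 11277 (24 h against 0 h), 8650 (48 h against 0 h) and 1698 (48 h against 24 h) in B73, to 8952 in the mutant at 24 h, to 1691 and 88 for the interactions and to 616 for the average. In fits of only the groups compared they were 18, 1 and 4 for the genotypes, 0 for 48 h against 24 h in B73, 587 for 24 h against 0 h and 1682 for 48 h against 24 h in the mutant, and 6 and 5 for the interactions. With limma-voom on recovered reads they moved to 52 and 23 for the genotypes at 24 and 48 h, 457 for 48 h against 24 h in B73 and 0 for the interaction at 48 h. Without the filter they were 112 for the genotypes at 0 h and 28 and 24 for the interactions, and with a pseudocount of 0.1 they were 31 at 0 h and 0 for the interaction at 24 h. With library-total scaling they moved to 26 for the genotypes at 48 h, 523 for 48 h against 24 h in B73 and 10 for the interaction at 24 h, which was also 3 with quantile normalization and 2 without organelle genes. Other gene counts under these settings stayed within 1.5 times of those reported.

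With single libraries left out, counts of called genes ranged from 25 to 54, 24 to 208 and 36 to 183 for the genotypes at 0, 24 and 48 h. In B73 they ranged from 930 to 1975 (24 h against 0 h), 3020 to 5542 (48 h against 0 h) and 223 to 1101 (48 h against 24 h). In the mutant they ranged from 883 to 3524, 6231 to 7144 and 2953 to 4970 in the same order. The interactions ranged from 0 to 8 and from 2 to 5, and the average from 88 to 191.

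With the correlation estimated, 0 lists passed in each of the 12 comparisons, against 5 to 18 with the preset correlation (1 to 5 lists per comparison at an unadjusted p under 0.05). Leaving out single libraries gave 6 to 11, 7 to 21 and 5 to 14 lists for the genotypes, 9 to 13, 6 to 9 and 3 to 17 in B73, 7 to 9, 3 to 9 and 5 to 8 in the mutant, 7 to 20 and 1 to 10 for the interactions, and 4 to 7 for the average. With library-total scaling 3 lists passed for 48 h against 24 h in B73 in place of 8, and 8 for the interaction at 48 h in place of 5. With the 5 transcription factor lists by description, 10 lists passed for 48 h against 0 h in the mutant in place of 5. The genes called in the average gave 2 windows of 5 Mb. The 6 genes called at all 3 times gave 0, a set too small to set against it.

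Libraries with the same replicate number did not deviate together. Of 45 such pairs, 14 had a correlation over 0.1 (median 0.0306, against -0.00673 for pairs with different numbers), and 5 libraries correlated best with their own number. With the replicate number as a block, the counts were 47, 77 and 73 genes for the genotypes, 2100, 5326 and 711 in B73, 2246, 8339 and 5085 in the mutant, 0 and 2 for the interactions and 139 for the average. The block also ended the calls of the calcium list at 24 h (adjusted p = 0.0557) and of the membrane lipid and vascular lists at 48 h (0.0532 each) between genotypes.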

Other observations

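In this part the position test on the genes called in the average, the chance placement and merging tests, and the tests of a 0 h sample and of low depth for mutant 24 h replicate 2 were chosen after the result was seen, as were the lists by description. Lists by description passed in several comparisons. At 48 h against 0 h in the mutant, of 119 ethylene-responsive factors, 44 rose, 13 fell and 62 did not pass. They numbered 45 and 14 adjusted over the list alone (camera adjusted p = 0.00344, adjusted p = 0.802 with an estimated correlation). In B73, 33 rose and 6 fell (camera adjusted p = 0.00182, adjusted p = 0.726 with an estimated correlation). At 48 h against 0 h in the mutant, of 83 WRKY genes, 29 rose, 7 fell and 47 did not pass. The counts were 29 and 7 adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.802 with an estimated correlation). In B73, 19 rose and 4 fell (camera adjusted p = 0.0102, adjusted p = 0.726 with an estimated correlation). Of 68 NAC genes, 14 rose and 2 fell at 24 h (camera adjusted p = 0.000267, adjusted p = 0.325 with an estimated correlation) and 17 rose and 3 fell at 48 h in B73 (camera adjusted p = 0.00620, adjusted p = 0.726 with an estimated correlation). Of 169 MYB genes, 15 rose and 7 fell at 24 h in B73 (camera adjusted p = 0.0160, adjusted p = 0.452 with an estimated correlation). At 24 h 4 of these lists were lower in the mutant than in B73, WRKY (0 genes higher, 2 lower), ethylene-responsive (0 and 1), NAC (0 called) and MYB (1 and 0), with camera adjusted p from 0.000637 to 0.0299 (adjusted p from 0.537 to 0.648 with an estimated correlation). Mutant 24 h replicate 2 was lowest of its group in all 4 (ethylene-responsive 2.29, others 2.98 and 3.36, B73 mean 3.20). The NAC list was shifted higher at 0 h (camera adjusted p = 0.0176, adjusted p = 0.782 with an estimated correlation) and the WRKY and NAC lists lower in the interaction at 24 h (camera adjusted p = 4.46e-05 and 0.000194, adjusted p = 0.427 with an estimated correlation), with 0 called.

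Genes called between mutant and B73 in the average over the times gathered in 2 of 426 windows of 5 Mb. Chromosome 7 from 10000001 to 15000000 held 9 called genes of 50 tested (adjusted p = 1.33e-08), and chromosome 6 from 5000001 to 10000000 held 7 of 38 (adjusted p = 9.40e-07), together 10.8% of the 148 placed genes. They included Zm00001d019002 (log2 fold change -4.83), histone H2A.5 (Zm00001d019045, 1.93), FKBP16-4, a chloroplast peptidyl-prolyl isomerase (Zm00001d019052, -1.82), psbY of photosystem II (Zm00001d035135, -2.21) and COP9 signalosome subunit 3 (Zm00001d035130, -1.33). Genes drawn singly at random gave at most 12 in windows of at least 5 called genes, against 16. The share of 10000 sets was 1e-04, the smallest possible, which argues against independent placement only. Merging called genes within 100 kb left 15 (share 1e-04) but used distance, so copies stay open. The titles place the mutant in the B73 background, and sequence was not examined. A linked segment that differs in sequence between the lines is a candidate explanation, since the 72 uncalled genes of the windows had a median absolute moderated t of 1.76 against 0.817 in random sets (percentile 100), and effects of the mutation on nearby genes stay open.

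Mutant 24 h replicate 2 lay between the 0 h and the other 24 h libraries. Over all tested genes it correlated best with B73 0 h replicate 2 (r = 0.857), mutant 0 h replicate 1 (0.856) and B73 24 h replicate 1 (0.849). The other libraries of its group stood at 0.846 and 0.818, and the other 0 h libraries between 0.806 and 0.828. Its description field gives 0 h, as do those of 3 other mutant libraries of 24 and 48 h. On the 2164 genes that changed between 24 h and 0 h in B73 it stood 0.756 log2 units above the highest mutant 0 h library, where those libraries had an SD of 0.0702, which argues against a 0 h sample under its label. On 7 genes called between genotypes at 0 and 48 h it stood 2.37 log2 units above the highest B73 library (SD 0.161), which argues against a B73 sample. It had 1.26 M reads more than the deeper of the other libraries of its group, which argues against low depth. A weaker or later response of these seedlings and a mixture of samples were not tested and stay open.

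More genes were called between 48 h and 0 h in the mutant (8438) than in B73 (5374). On the same 2164 genes the mutant at 48 h stood 0.250 log2 units above B73 at 48 h (two-sided exact permutation p = 0.3, n = 3, where the smallest possible p is 0.1). The mutant was above B73 on these genes at 0 h too (-1.26, -1.13 and -1.23 against -1.36, -1.37 and -1.31), but the B73 0 h libraries helped to choose these genes, so that gap cannot be weighed. Whether a larger change after 48 h in the mutant accounts for the count stays open with 3 libraries per group. Over all tested genes the log2 fold changes from 0 to 48 h had an SD of 1.40 in the mutant and 1.17 in B73.

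With 3 against 3 libraries there are 10 splits, so a share under 0.05 cannot be reached. The real and highest other counts of genes were 49 and 7, 95 and 12, and 77 and 136 for the genotypes at 0, 24 and 48 h, where 1, 1 and 2 splits reached the real count. They were 2164 and 4, 5374 and 1, and 806 and 21 in B73 for 24 h against 0 h, 48 h against 0 h and 48 h against 24 h, and 2216 and 13, 8438 and 3, and 5198 and 4 in the mutant, with 1 split each. For the average, 1 of 100 splits reached 151 genes, the real one (highest other 25), the lowest share 100 splits can give. For lists the real and highest other counts were 6 and 16, 16 and 18, and 13 and 12 for the genotypes (9, 3 and 1 splits), 10 and 21, 7 and 12, and 8 and 18 in B73 (6, 7 and 5 splits), and 8 and 18, 5 and 15, and 7 and 14 in the mutant (6, 8 and 7 splits). For lists in the average, 72 of 100 splits reached the real 6 (highest other 21), so chance is not excluded.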
